A study of Mus musculus with 6 samples.

How the data were processed

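RNA sequencing libraries of B cells sorted from mouse colons were compared between mice given lenvatinib and mice given DMSO, the solvent control, with 3 libraries in each group. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a VAHTS Universal V10 kit. Per the submitters' processing notes, reads were counted with HTSeq against the mouse genome build GRCm39. The aligner, the annotation, the HTSeq version and the use of strand were not given in the sources used here. The authors deposited FPKM values, fragments counted per gene divided by gene length and library total, and 20591 gene symbols in 1 table with 6 value columns were used here. Each column was matched to its sample by the column name written in that sample's description, and no column was left unused. Symbols are used as the table gives them, and no coordinates are printed because the reference at hand is of another build than the authors'.

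FPKM is not a count, so the tests were run on a log scale. FPKM values were scaled per library by median-of-ratios factors, taken from genes with FPKM of at least 1 in every library. These factors lay between 0.992 and 1.009. Genes with scaled FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 9937 genes. The values log2(scaled FPKM + 1) were fitted with treatment as the only term in limma 3.58.1 under R 4.3.3, with a mean-dependent trend and robust empirical Bayes moderation. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. A fold change on this scale understates the change of genes with low FPKM, so the scaled FPKM of both groups is given beside it.

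A total of 37 gene lists, among them markers of 11 other cell types, were fixed before the data were examined, as were the tests, the main settings and the alternatives not described as added. Lists with at least 3 tested members, 29 in all, were tested with camera from limma on the same fit, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 29 lists. Each list was also tested with a correlation estimated from the residuals. The mean log2(scaled FPKM + 1) of all members of 13 lists, those of other cell types, B cell identity and plasma cells, was compared between groups by an exact permutation test. With 3 libraries against 3 that test cannot give a p below 0.1, and it therefore cannot pass a threshold of 0.05.

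The genes named one by one follow a rule. Among genes past the threshold whose 3 lenvatinib libraries all lay above, or all below, the 3 DMSO libraries, the 12 with the largest rise and the 12 with the largest fall were taken. Predicted genes were counted but not named, which left out 31 that rose and 42 that fell, and immunoglobulin segments were not used here. From each list up to 4 tested members with the smallest p were added, and a gene named outside the rule is said to have been chosen after its values were seen.

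The depth of each library was worked out from the FPKM steps. For a library, the values of a gene are whole multiples of what 1 read is worth for that gene's length, and 1 total of reads per library made them whole to a tolerance of 1e-05. Whole reads were recovered this way for 19434 of the 19715 genes with any value, 98.6 percent. The totals were 26635279, 31238096 and 30153561 reads for DMSO replicates 1, 2 and 3, and 31655500, 28835836 and 27605518 reads for lenvatinib replicates 1, 2 and 3. The gene lengths recovered for 13 mitochondrial protein genes equalled the annotated lengths in 13 of 13 cases. The recovered reads served to compare the replicates with counting noise and for 1 added alternative, limma-voom.

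The procedures were tested on simulated data with known answers. Each simulated gene was given the smoothed spread of genes of its mean level, so genes of equal level did not differ in spread as real ones can. With 200 of 9937 genes changed, the gene test recovered 62 percent of changes of 0.3 on the log2 scale with 5 false calls. It recovered 89.5 percent of changes of 0.5 with 10 false calls, and 100 percent of changes of 1 with 7 false calls. Recovery and false calls may therefore be less favourable in the real data. The list test called the 1 shifted list and 0 of 28 others. The simulated genes varied independently of each other, so this says nothing about false calls where the members of a list vary together. In the data the estimated correlation was 0.5 for cytosolic ribosomal proteins and 0.3 for erythroid cells. The read recovery returned 6 of 6 simulated totals. It gave the exact reads of 99.24 percent of the 9918 simulated genes with FPKM of at least 1 in at least 3 libraries. Genes below that level were not part of this share.

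The alternatives were other pseudocounts, other filters on low values, 4 other scalings, a replicate term in the fit, a fit with neither trend nor robust moderation, weights per library, other list tests and leaving out each library in turn. Added after seeing the data were limma-voom on the recovered reads, a test against a minimum log2 change of 0.5, and the mitochondrial genes as 1 more list. The share of immunoglobulin transcripts and the heavy chain isotypes, both planned, were not analysed here, and T cell receptor constant genes were not used here. A planned single-gene result is not reported here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the read recovery and the figures.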

Results

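Gene expression was measured by RNA sequencing in B cells sorted from the colons of mice that received lenvatinib or DMSO, with 3 libraries per group. Lenvatinib is an oral inhibitor of receptor tyrosine kinases, chiefly those for the growth factors VEGF and FGF, with PDGFRA, KIT and RET, and DMSO is the solvent in which it was given. The series title places the comparison in a study of how lenvatinib affects intestinal inflammation and the entry of B cells into the gut. The sample labels state the treatment but no inflammatory state of the mice, and they number the libraries as biological replicates without saying whether each came from a separate animal. The p-values below therefore measure the spread between these libraries, which may be technical. Each library held between 26635279 and 31655500 gene-assigned reads, and the 10 most abundant genes took between 6.4 and 6.97 percent of them, a share that leaves aside immunoglobulin segments, which were not used here. Replicates were close to each other, with correlations of log values across genes of 0.9932 to 0.994 within groups against 0.9836 to 0.9845 between groups. Genes are not independent replicates, so these correlations describe the libraries only. All values after ± are SDs over n = 3 libraries, in scaled FPKM.

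The most evident differences in the lenvatinib libraries were lower expression of interferon-inducible genes and higher expression of T cell, natural killer cell and colon epithelial genes, with a smaller fall of B cell genes. Of 9937 tested genes, 1854 (18.7 percent) passed the limma test at an adjusted p of 0.05, with 1038 higher and 816 lower in the lenvatinib group. The balance depended on the scaling: 859 were higher and 978 lower when scaled to the sum of FPKM, 853 and 984 when that sum left out mitochondrial genes, 919 and 934 with quantile normalization, and 1181 and 721 with FPKM as deposited. The changes were mostly small, with a median size of 0.31 on the log2 scale, and 136 genes changed by at least 1, of which 122 were higher and 14 lower. The groups did not overlap for 3690 genes, 37.1 percent of those tested, where chance gives 10 percent. Leaving out lenvatinib replicate 1 or 2 lowered the number of genes called higher to 680 or 673. The number called in all fell to 122 when changes were tested against a minimum of 0.5 on the log2 scale, a test added after seeing the data.

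**Figure D1:**
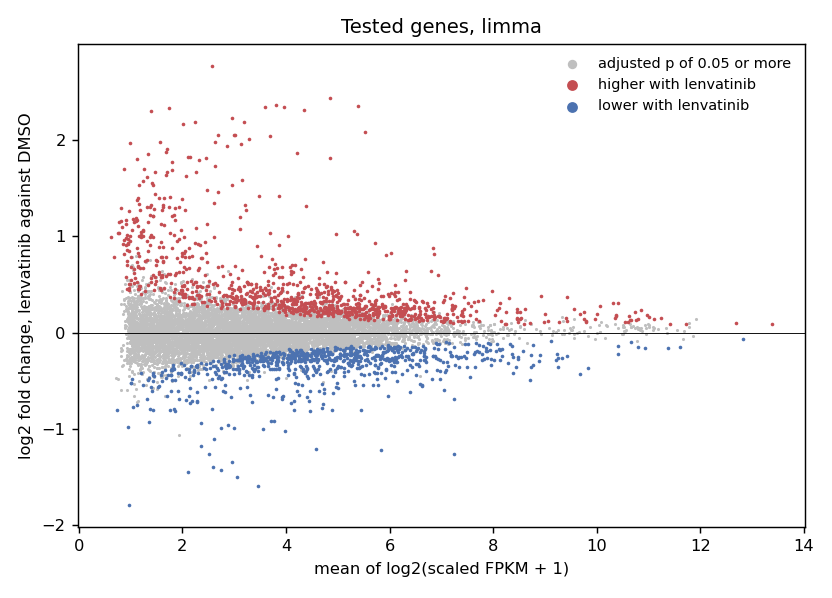
Log2 fold change of each tested gene, lenvatinib against DMSO, plotted against its mean log2(scaled FPKM + 1) over the 6 libraries. Red and blue points mark the 1038 genes higher and the 816 genes lower at a limma adjusted p of 0.05, and grey points the rest; 122 genes rose by at least 1 and 14 fell by at least 1.

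Of the 12 genes with the largest rise, 3 belonged to the T cell list, 1 to the list for natural killer and innate lymphoid cells and 2 to the colon epithelium list, and 6 to none of the lists. Car1, a carbonic anhydrase of colon epithelial cells, rose from 1.3 ± 0.347 to 14.6 ± 1.65, a log2 change of 2.77 (SE 0.13, limma adjusted p = 2.66e-06). Xcl1, a chemokine of natural killer and CD8 T cells, rose from 11.5 ± 2.61 to 65.7 ± 2.54, and Cd7, a surface protein of T and natural killer cells, from 17.7 ± 1.72 to 93.8 ± 6.92. Klrd1 and Klra7, both lectin-like receptors of natural killer cells, rose from 5.29 ± 1.28 to 30.9 ± 2.92 and from 4.42 ± 0.94 to 26.4 ± 3.25. Ctsw, a protease of cytotoxic lymphocytes, reached 34.1 ± 2.76 from 5.94 ± 0.806. The 3 Cd3 genes, which encode the signalling chains of the T cell receptor, rose by 2.31 for Cd3g, 2.23 for Cd3e and 2.19 for Cd3d on the log2 scale. The goblet cell lectin Zg16 rose from 0.496 ± 0.145 to 6.71 ± 1.98, the antimicrobial lectin Reg3b from 1.22 ± 0.282 to 9.08 ± 0.965, and the peptide transporter Slc15a2 from 0.196 ± 0.162 to 4.87 ± 0.338. The limma adjusted p of these 12 genes was at most 3.86e-05. Klra7 belongs to a family of closely related genes whose reads the counting could split, so its value is uncertain.

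Of the 12 genes with the largest fall, 8 belonged to the interferon response list. Oas2, an oligoadenylate synthetase that senses viral RNA, fell from 18.2 ± 0.865 to 5.43 ± 0.906, a log2 change of −1.59 (SE 0.1, limma adjusted p = 1.26e-05), and its relatives Oas3 and Oasl2 changed by −1.45 and −1.26. The antiviral RNA-binding genes Ifit3 and Ifit2 fell from 13 ± 0.794 to 3.97 ± 0.55 and from 11.4 ± 0.584 to 3.94 ± 0.668. Irf7, the transcription factor that amplifies type I interferon responses, fell from 86.6 ± 2.62 to 36.7 ± 1.51, and Ifi27l2a, an interferon-induced gene, from 233 ± 21 to 96.9 ± 0.52. Usp18, a feedback inhibitor of interferon signalling, changed by −1.18 (SE 0.186, limma adjusted p = 0.00222). The other 4 were Slfn5, Ifi213 and Ifitm3, which interferon also induces, with log2 changes of −1.43, −1.21 and −1.02, and the heparan sulfate proteoglycan Sdc3 with −1.11. In the test against a minimum log2 change of 0.5, Ifitm3 and Usp18 did not pass.

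**Figure D2:**
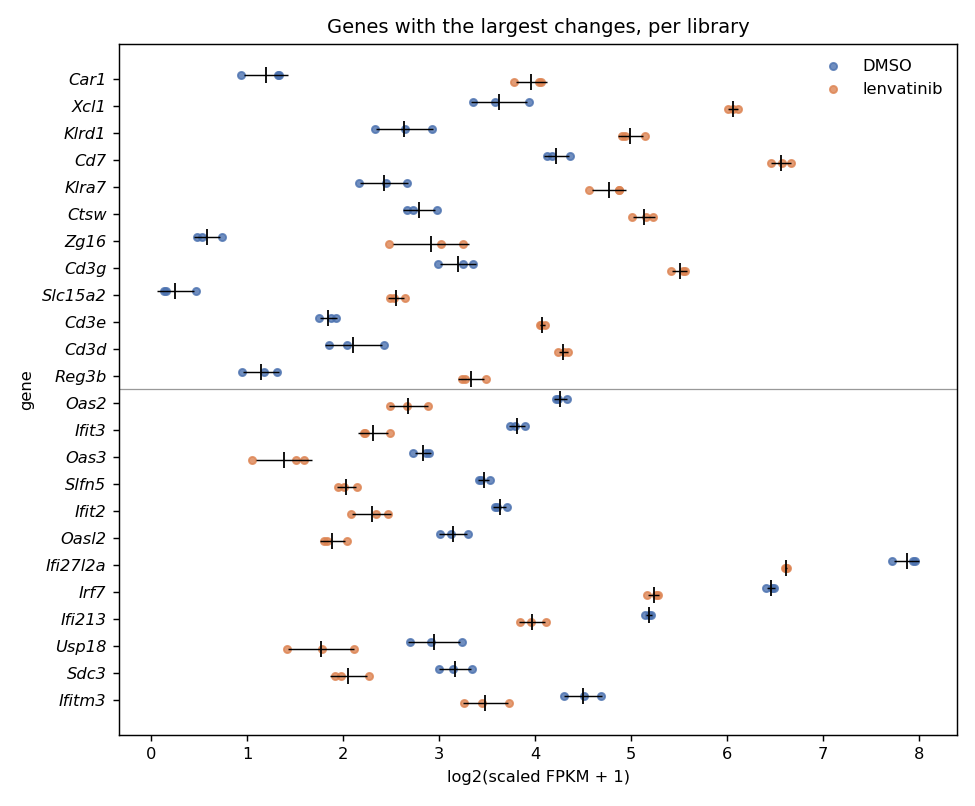
Expression of the 12 genes with the largest rise, above the line, and the 12 with the largest fall, below it, as log2(scaled FPKM + 1). Each point is 1 library, with 3 per group; vertical ticks mark the group means and horizontal bars 1 SD, and in each gene the 3 lenvatinib libraries lie apart from the 3 DMSO libraries.

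The interferon response list as a whole was lower. Of 24 tested members 22 fell and 1 rose, with 23 lower and 1 higher when adjusted over the list alone, and the median log2 change was −0.77 (camera adjusted p = 8.11e-20). The member that rose was Gbp2, an interferon-induced guanylate-binding protein, from 6.21 ± 0.891 to 8.77 ± 0.134. The member that did not pass was Ifih1, with 1.94 ± 0.463 in DMSO and 1.36 ± 0.0407 in lenvatinib libraries. Both were named after their values were seen. The list changed in libraries whose T cell, natural killer and epithelial markers were higher and whose B cell identity genes were lower, as given next.

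Markers of T cells, natural killer cells and colon epithelium were higher with lenvatinib. In the T cell list 10 of 12 tested genes rose and 0 fell, 10 and 0 also when adjusted over the list alone, with a median log2 change of 1.08 (camera adjusted p = 1.13e-09). Cd8a rose from 2.39 ± 0.073 to 10.3 ± 1.37. The 2 members that did not pass, named after their values were seen, were Cd4, at 1.25 ± 0.232 and 1.27 ± 0.188, and Cd8b1, at 1.76 ± 0.456 and 1.39 ± 0.318. In the list for natural killer and innate lymphoid cells 6 of 6 tested genes rose, likewise 6 adjusted over the list alone, with a median of 1.71 (camera adjusted p = 1.91e-08). Among them were Nkg7, a granule protein, from 5.42 ± 1.23 to 25.1 ± 0.552, the granule protease Gzma from 4.07 ± 1.7 to 18.7 ± 1.07, and the receptor Klrk1 from 1.11 ± 0.329 to 4.56 ± 0.341. In the colon epithelium list 9 of 9 tested genes rose, 9 adjusted over the list alone, with a median of 1.64 (camera adjusted p = 5.58e-12). The keratin Krt19 rose from 0.689 ± 0.206 to 5.21 ± 0.363 and the lectin Lgals4 from 5.82 ± 0.264 to 17.3 ± 2.45. These medians depended on which genes were tested, since a gene could pass the filter through its lenvatinib libraries alone. Of the tested epithelial genes Krt8, Krt19, Cdh1, Tff3 and Guca2a had DMSO means below 1, from 0.596 to 0.871. In the natural killer list Klrb1c had a DMSO mean of 0.433. For such genes a rise was close to a condition of being tested. Without a filter on low values they were 0.62 for T cells, 0.8 for natural killer and innate lymphoid cells and 0.91 for colon epithelium. The T cell median was 1.96 with a mean filter of 5, and the epithelial one 2.5 with a pseudocount of 0.1 and 2.58 with limma-voom.

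Lists of myeloid markers had smaller medians. In the macrophage and dendritic cell list 3 of 11 tested genes rose and 0 fell, 4 and 0 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.0313, and 0.271 as the adjusted p with an estimated correlation). Apoe, an apolipoprotein, rose from 140 ± 6.13 to 160 ± 2.44, a call lost in limma without trend and robust moderation (adjusted p = 0.0614). This list also lost its call without lenvatinib replicate 1 (camera adjusted p = 0.0772), with a mean filter of 5 (adjusted p = 0.0675) and with limma-voom (adjusted p = 0.0662). In the neutrophil list 4 of 5 tested genes rose and 0 fell, 4 and 0 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.0059, and 0.119 as the adjusted p with an estimated correlation). The median was 0.82 without lenvatinib replicate 3 and 0.13 without a filter on low values. Retnlg, a resistin-like gene of neutrophils, stood at 0.478 ± 0.774 and 2.64 ± 0.712 (limma adjusted p = 0.0126, and 0.0654 without a filter on low values). Plasmacytoid dendritic cell genes as a list did not pass, with 1 higher and 1 lower of 6 tested, the same numbers adjusted over the list alone, and a median of −0.1 (camera adjusted p = 0.456). Its mean change, 0.03, had the opposite sign, and the median was −0.03 without lenvatinib replicate 1, −0.01 with limma-voom and 0.11 without a filter on low values. Erythroid genes did not pass either, with 1 higher of 3 tested, 2 adjusted over the list alone (camera adjusted p = 0.115), and the globin copies can share reads. They passed without a filter on low values (camera adjusted p = 0.00356), without lenvatinib replicate 1 (adjusted p = 0.0198) and in fry (adjusted p = 0.0499).

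By the mean log2(scaled FPKM + 1) of all list members, tested or not, the groups did not overlap for 11 of 13 lists, and each of these had the smallest exact permutation p that 3 against 3 allows, 0.1 (adjusted p = 0.118). The mean level was higher with lenvatinib by 1.07 for T cells, 0.99 for natural killer and innate lymphoid cells and 1.1 for colon epithelium. The differences were 0.56 for erythroid cells, 0.33 for neutrophils, 0.19 for macrophages and dendritic cells and 0.19 for fibroblasts and smooth muscle. They were 0.18 for mast cells, 0.12 for endothelium and 0.09 for plasmacytoid dendritic cells. In the mast cell list only Kit was higher, from 1.75 ± 0.668 to 8.33 ± 0.269. Cpa3, Mcpt1, Mcpt4, Cma1 and Hdc, named after their values were seen, had lower means with lenvatinib. In the endothelial list the tested gene, Pecam1, fell, and every other member had group means below 1. B cell identity genes had a lower mean, by −0.22. Plasma cell genes (difference 0, exact permutation p = 0.9) and genes of enteric neurons and glia (difference −0.05, exact permutation p = 0.6) overlapped between the groups. With a pseudocount of 0.1 the mast cell difference became −0.26 and 10 of the other differences grew, among them those for T cells to 1.3, natural killer and innate lymphoid cells to 1.5 and colon epithelium to 2.11.

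Genes that define B cells were modestly lower in the same libraries. In the B cell identity list 16 of 19 tested members fell and 0 rose, the same numbers adjusted over the list alone, with a median log2 change of −0.24 (camera adjusted p = 7e-12). Cd79a, a signalling chain of the B cell receptor, fell from 1040 ± 21.6 to 802 ± 20.9, the complement receptor Cr2 from 75.8 ± 1.21 to 56.7 ± 1.7, the transcription factor Spib from 144 ± 4.42 to 109 ± 4.11 and the inhibitory receptor Cd22 from 174 ± 1 to 145 ± 1.56. The 3 that did not pass, named after their values were seen, were Blk at 132 ± 1.28 and 137 ± 1.15, Cxcr5 at 125 ± 0.399 and 124 ± 2.96, and Cd37 at 368 ± 3.8 and 354 ± 8.05. In the list for MHC class II and costimulation 10 of 14 tested genes fell and 0 rose, 11 and 0 adjusted over the list alone, with a median of −0.16 (camera adjusted p = 1.77e-06). H2-Ob, a regulator of peptide loading, fell from 391 ± 5.82 to 324 ± 3.51 and H2-Eb1, a class II chain, from 2070 ± 34.9 to 1850 ± 17.6. The call of H2-Eb1 was lost in limma without trend and robust moderation (adjusted p = 0.0662). In the list for B cell receptor signalling 15 of 21 tested genes fell and 0 rose, 16 lower and 1 higher adjusted over the list alone, with a median of −0.18 (camera adjusted p = 8.99e-10, and 0.0683 as the adjusted p with an estimated correlation). Its lowest p belonged to the adaptor Pik3ap1, which fell from 203 ± 6.16 to 158 ± 1.45, and to Malt1, a protease of the pathway to NF-kB, which fell from 144 ± 2.26 to 116 ± 1.15. Of the 21 genes of this list in the table, 5 are also in the B cell identity list.

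Cytokine and chemokine genes were higher, beside the rise of T cell and natural killer markers. In the inflammatory list 12 of 17 tested genes rose and 1 fell, 12 and 1 adjusted over the list alone, with a median log2 change of 0.73 (camera adjusted p = 2.97e-07). Ccl5, a chemokine of activated T and natural killer cells, rose from 21.7 ± 3.68 to 94.4 ± 10.4 and Ifng, which encodes interferon gamma, from 1.37 ± 0.123 to 7.34 ± 0.775. The interleukin genes Il1a and Il1b rose from 1.44 ± 0.219 to 4.47 ± 0.427 and from 21.4 ± 1.89 to 33.7 ± 3.23. The member that fell, named after its value was seen, was the lymphotoxin gene Ltb, from 92.3 ± 1.47 to 79.3 ± 2.2. Il6 and Csf2, also named after their values were seen, had DMSO means of 0.376 and 0.273. For both a rise was close to a condition of being tested. Without a filter on low values the median of the inflammatory list was 0.61. Its member Il22 is also in the list for natural killer and innate lymphoid cells.

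Stress and metabolic genes were also higher, in libraries whose marker levels were higher by 1.07 for T cells, 0.99 for natural killer and innate lymphoid cells and 1.1 for colon epithelium. In the heat shock list 11 of 13 tested genes rose and 0 fell, 13 and 0 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 2.13e-12). The chaperone genes Hspd1, Hsph1, Hspe1 and Dnaja1 rose from 423 ± 5.35 to 552 ± 3.85, from 280 ± 4.45 to 359 ± 1.53, from 604 ± 13.7 to 780 ± 16 and from 217 ± 2.68 to 292 ± 11.3. In the glycolysis and hypoxia list 15 of 25 tested genes rose and 1 fell, 18 and 1 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 2.02e-09). Lactate dehydrogenase Ldha rose from 45.3 ± 0.565 to 80 ± 2.84, the glycolytic enzymes Tpi1 from 37.4 ± 1.83 to 72.2 ± 1.66, Pgk1 from 63.1 ± 1.75 to 99.2 ± 1.2 and Eno1 from 88.3 ± 2.8 to 138 ± 6.55. The member that fell, named after its value was seen, was the glucose transporter Slc2a1, from 60.8 ± 1.08 to 47.3 ± 1.26.

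Nuclear genes of oxidative phosphorylation rose in 30 of 73 tested cases and fell in 0, 37 and 0 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 2.93e-09, and 0.0964 as the adjusted p with an estimated correlation). Atp5b, a subunit of ATP synthase, rose from 282 ± 5.14 to 328 ± 3.91. Of the cytosolic ribosomal protein genes 19 of 82 rose and 0 fell, 25 and 0 adjusted over the list alone, with a median of 0.06 (camera adjusted p = 9.56e-07, and 0.421 as the adjusted p with an estimated correlation). That median was 0.02 without DMSO replicate 3 and with quantile normalization. Rps2 rose from 1580 ± 17.9 to 1830 ± 32.6, and reads of ribosomal genes can be shared with their pseudogenes. Proliferation genes rose in 5 of 24 cases and fell in 0, with 7 higher and 1 lower adjusted over the list alone and a median of 0.16 (camera adjusted p = 0.0137, and 0.134 as the adjusted p with an estimated correlation). Pcna, the sliding clamp of DNA replication, rose from 152 ± 1.99 to 196 ± 7.53. The 13 mitochondrially encoded protein genes, tested as a list added after seeing the data, had 1 higher, 1 lower and a median of −0.02 (camera adjusted p = 0.455).

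The lists for regulatory B cells, B-1 cells, IgA class switching and Toll-like receptors passed with the preset correlation and not with an estimated one. In the regulatory B cell list 7 of 19 tested genes rose and 2 fell, 9 and 3 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.0137, and 0.0964 as the adjusted p with an estimated correlation). The call was also lost with a mean filter of 5 (adjusted p = 0.0548) and with camera on ranks (adjusted p = 0.116). The members with the lowest p were Gzmb, a granule protease, Tigit and Ctla4, both inhibitory receptors of T cells, and the ectoenzyme Nt5e. They rose by 2.05, 2.05, 1 and 0.9 on the log2 scale, in libraries whose marker levels were also higher by 1.07 for T cells and 0.99 for natural killer and innate lymphoid cells. In the B-1 cell list 4 of 10 tested genes rose and 0 fell, 5 and 0 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 0.00155, and 0.0964 as the adjusted p with an estimated correlation). It holds Ctla4 as well, and Spn, a sialomucin also of T cells, which rose from 2.96 ± 0.152 to 5.31 ± 0.318. In the list for IgA class switching 5 of 14 tested genes fell and 1 rose, 6 and 1 adjusted over the list alone, with a median of −0.11 (camera adjusted p = 0.00835, and 0.0964 as the adjusted p with an estimated correlation). That median was −0.07 without DMSO replicate 2 and without lenvatinib replicate 2. Smad7, an inhibitor of TGF-beta signalling, fell from 46.4 ± 2.32 to 32.5 ± 0.161 and the receptor Tgfbr2 from 70 ± 1.61 to 57.1 ± 2.35. In the Toll-like receptor list 4 of 17 tested genes fell and 2 rose, 5 and 2 adjusted over the list alone, with a median of −0.07 (camera adjusted p = 0.0346, and 0.157 as the adjusted p with an estimated correlation). That median was −0.02 without lenvatinib replicate 2, −0.11 without lenvatinib replicate 3 and −0.12 when scaled to the sum of FPKM or by quantiles. The receptor Tlr7 fell from 16.1 ± 0.295 to 10.4 ± 0.566 and the adaptor Myd88 rose from 22 ± 0.465 to 26.4 ± 0.935. The camera adjusted p of this list was 0.0569 with a mean filter of 5, 0.0659 without DMSO replicate 1 and 0.0974 without lenvatinib replicate 2.

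The homing and trafficking list, which bears most directly on B cell entry into the gut, did not pass as a list (camera adjusted p = 0.456). Of 21 tested genes 4 rose and 6 fell, 5 and 8 adjusted over the list alone, with a median of −0.01 that became 0.01 with FPKM as deposited, a mean of 0.1 and a camera direction of lower. The median was 0.03 without DMSO replicate 3 or lenvatinib replicate 3, and fry called the list higher (adjusted p = 0.00952). Itgae, the integrin chain by which lymphocytes bind E-cadherin, rose from 1.3 ± 0.23 to 7.13 ± 0.443, in libraries whose marker levels were also higher by 1.07 for T cells and 0.99 for natural killer and innate lymphoid cells. The other members with the lowest p fell. The chemokine receptor Ccr7 went from 654 ± 3.49 to 540 ± 3.34, Cxcr4 from 241 ± 5.1 to 198 ± 3.91 and the sphingosine phosphate receptor S1pr1 from 86.1 ± 1.08 to 70.1 ± 2.6. The chains of the gut-homing integrin, chosen after their values were seen, were Itga4, which fell from 33.7 ± 1.53 to 28.1 ± 0.415, and Itgb7, at 15.2 ± 0.875 and 16.4 ± 0.615 (limma adjusted p = 0.3).

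Among the remaining lists, plasma cell genes had 3 higher and 5 lower of 18 tested, 3 and 6 adjusted over the list alone (median −0.08, camera adjusted p = 0.18). Within it Irf4, a transcription factor of activated B cells, fell from 136 ± 1.8 to 104 ± 0.537, and Jchain, the joining chain of secreted IgA and IgM, rose from 45.9 ± 2.49 to 62.9 ± 4.36. Germinal centre genes had 3 higher and 0 lower of 14, also when adjusted over the list alone (median 0.06, camera adjusted p = 0.204), with Rgs13, a regulator of G protein signalling, up from 2.93 ± 0.216 to 5.19 ± 0.229. NF-kB targets had 5 higher and 4 lower of 17, 6 and 4 adjusted over the list alone (median 0.05, camera adjusted p = 0.582). The NF-kB subunit Rel fell from 478 ± 5.88 to 372 ± 7.63. Immediate early genes had 4 higher and 6 lower of 22, 7 and 8 adjusted over the list alone (median −0.01, or 0.01 with FPKM as deposited, camera adjusted p = 0.328). Its mean, 0.01, was above 0 and its camera direction lower. Fosl2 rose from 20.9 ± 0.734 to 43.4 ± 1.53 and Egr1 fell from 118 ± 2.29 to 80.5 ± 3.25. Genes of the unfolded protein response and secretion had 5 higher and 1 lower of 24, 6 and 1 adjusted over the list alone (median 0.04, camera adjusted p = 0.172). The p53 targets had 1 higher and 3 lower of 11, 3 and 3 adjusted over the list alone (camera adjusted p = 0.682), with a median of 0.09 and a camera direction of lower. Cholesterol synthesis genes had 4 higher and 0 lower of 17, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.262). With 1 library left out the medians ranged from 0.04 (without DMSO replicate 3 or lenvatinib replicate 2) to 0.2 (without lenvatinib replicate 3) for p53 targets. They ranged from −0.13 (without DMSO replicate 3) to −0.02 (without lenvatinib replicate 3) for plasma cell genes and from 0 (without DMSO replicate 2) to 0.06 for NF-kB targets. Fry, which tests whether a list moves on balance and does not compare it with other genes, called 5 of these lists: plasma cell (adjusted p = 0.00129), germinal centre (0.00539), NF-kB targets (0.0201), unfolded protein response and secretion (0.00619) and cholesterol synthesis (0.000266).

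Of the kinases that lenvatinib inhibits, only Kit reached the expression needed for testing. It rose from 1.75 ± 0.668 to 8.33 ± 0.269, a log2 change of 1.79 (SE 0.155, limma adjusted p = 6.22e-05), while none of the other 9 had a group mean above 0.129. Kit is also in the mast cell list, whose other tested member Hdc stood at 1.27 ± 0.322 and 1.22 ± 0.761. In the endothelial list the tested gene was Pecam1, an adhesion molecule that leukocytes also carry, which fell from 42.3 ± 0.567 to 32.9 ± 0.16. In the list for fibroblasts and smooth muscle 1 of 2 tested genes rose, Acta2, at 0.749 ± 0.119 and 1.87 ± 0.635 (limma adjusted p = 0.0187, 0.061 without DMSO replicate 3 and 0.0607 without a filter on low values). The immunoglobulin constant and variable gene lists were not analysed here.

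Of the 29 tested lists, 19 passed in camera with the preset correlation, 13 higher and 6 lower. Fry called 25. With an estimated correlation 9 passed. These were the lists for B cell identity, interferon response, MHC class II, heat shock, glycolysis and hypoxia, inflammatory cytokines, T cells, natural killer and innate lymphoid cells, and colon epithelium.

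**Figure D3:**
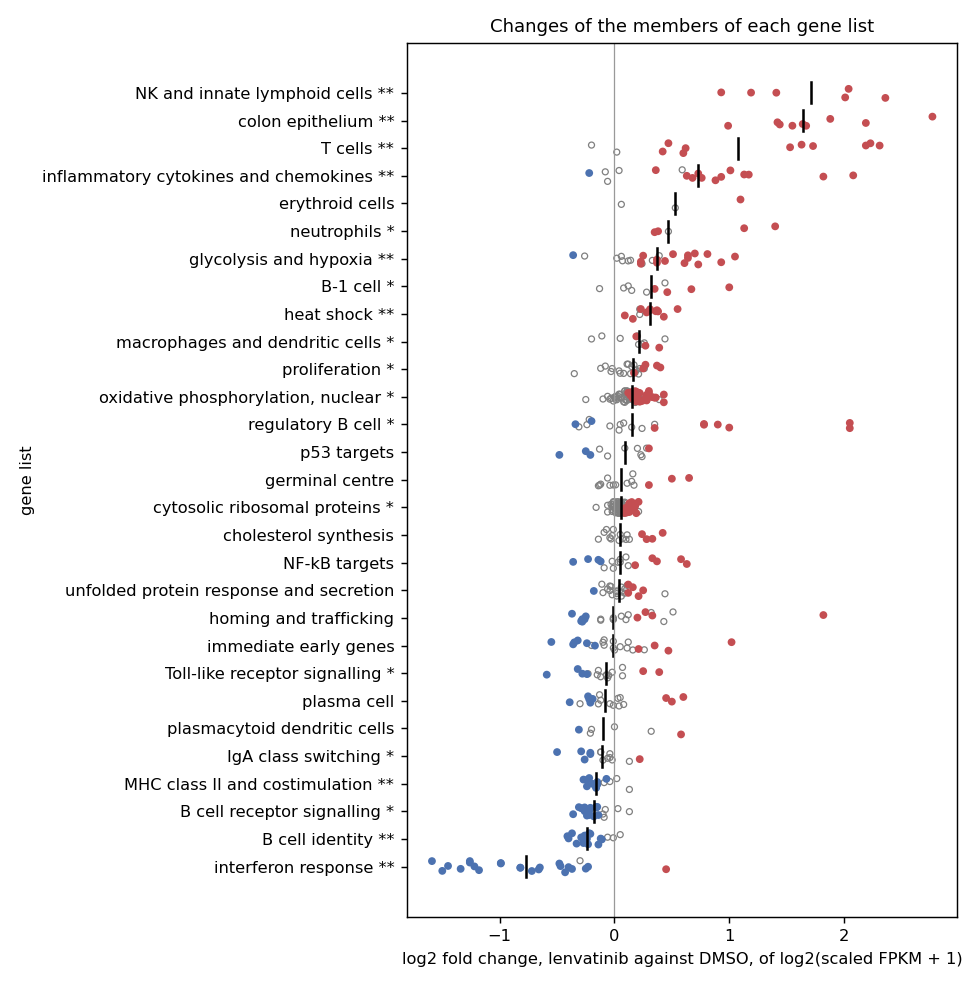
Log2 fold changes, lenvatinib against DMSO, of the tested members of the 29 lists, ordered by their median, which a black line marks. Red and blue points passed the limma test as higher or lower and open points did not; 1 asterisk marks the 19 lists that passed in camera with the preset correlation and a second asterisk the 9 that also passed with an estimated one.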

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

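The limma-voom fit, the test against a minimum change and the mitochondrial list were chosen after seeing the data. The count of 1854 genes was between 1264 and 1902 under other pseudocounts, filters, scalings, moderation and weights, and between 1236 and 1418 when 1 library was left out, where fewer samples enter. Genes called higher ranged from 673 to 827 and genes called lower from 563 to 632 with 1 library left out. limma-voom on the recovered reads called 2454 genes, 1718 of them among the 1844 main calls that it tested. A minimum log2 change of 0.5 left 122 genes, 102 higher and 20 lower, by its own construction. The share of calls that were higher, 56 percent, lay between 46.4 and 62.1 percent under the other scalings, which left the median log2 change of all genes between −0.018 and 0.023. The replicate numbers did not pair the libraries: same-numbered libraries had correlations of −0.007, 0.006 and −0.005 between their deviations from the group means, and not every library correlated best with its own number. With a replicate block 1542 genes passed, 1465 of them shared with the main calls.

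Of the 24 genes with the largest changes, each kept its call under every alternative that tested it, except Ifitm3 (adjusted p = 0.1) and Usp18 (0.165) under the minimum change. Of the other 109 named list members, between 0 and 14 lost their call under a single alternative, at most 1 gained one and 0 reversed, with the minimum change left aside. There 82 lost it.

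With an estimated correlation 9 lists passed in place of 19. The adjusted p was then 0.0683 for B cell receptor signalling, 0.0964 for IgA class switching, regulatory B cells, B-1 cells and oxidative phosphorylation, 0.119 for neutrophils, 0.134 for proliferation, 0.157 for Toll-like receptors, 0.271 for macrophages and dendritic cells and 0.421 for ribosomal proteins. With a mean filter of 5, which tests fewer genes, it was 0.0548 for regulatory B cells, 0.0569 for Toll-like receptors and 0.0675 for macrophages and dendritic cells. Fry, which does not compare a list with other genes, called 25 lists, gaining 7: homing and trafficking (0.00952), as higher where camera had it lower, plasma cell (0.00129), germinal centre (0.00539), NF-kB targets (0.0201), unfolded protein response and secretion (0.00619), cholesterol synthesis (0.000266) and erythroid cells (0.0499). It gave 0.0987 for ribosomal proteins, camera on ranks gave 0.116 for regulatory B cells and limma-voom 0.0662 for macrophages and dendritic cells. With 1 library left out, the adjusted p for Toll-like receptors ranged from 0.0236 to 0.0974 and for macrophages and dendritic cells from 0.00653 to 0.0772. For the lists lost under a filter, fry, ranks or limma-voom the cause was not tested. Erythroid cells also passed without a filter (0.00356) and without lenvatinib replicate 1 (0.0198). Without a filter the list medians fell to 0.62 for T cells, 0.8 for natural killer and innate lymphoid cells, 0.91 for colon epithelium and 0.13 for neutrophils. The T cell median was 1.96 with a mean filter of 5, the epithelial one 2.58 with limma-voom, and the neutrophil one 0.82 without lenvatinib replicate 3. With a pseudocount of 0.1 the mast cell marker level reversed to −0.26 and 10 others grew by more than the spread between replicates, from 0.12 to 0.5 for endothelium and from 1.1 to 2.11 for colon epithelium, for example. The B cell identity level, −0.22, was −0.2 with FPKM as deposited and −0.21 without lenvatinib replicate 1. Alternatives for the immunoglobulin share and the heavy chain isotypes were not run, and the scaling planned without immunoglobulin and mitochondrial genes left out the mitochondrial genes alone. Exact tests of marker levels cannot pass a threshold of 0.05 at this size. By the chosen filter, genes without a scaled FPKM of at least 1 in at least 3 libraries were not tested in the main fit.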

Other observations

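All tests described here were chosen after the results they bear on had been seen, in the case of the conventional T cell genes after the values of Cd4, Cd5, Cd28 and the Cd3 genes. Of 10 genes listed for conventional T cells, 7 were tested and 5 rose, with a median log2 change of 0.6 against 2.23 for Cd3d, Cd3e and Cd3g. Icos and Cd27, costimulatory receptors, rose from 1.3 ± 0.327 to 4.28 ± 0.383 and from 1.14 ± 0.391 to 3.62 ± 0.492. The transcription factors Tcf7 and Lef1 rose from 1.03 ± 0.151 to 3.43 ± 0.4 and from 0.637 ± 0.112 to 1.24 ± 0.0244. Cd5 was at 1.22 ± 0.32 in DMSO and 1.33 ± 0.118 in lenvatinib libraries and did not pass.

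The first pattern is the joint rise of T cell, natural killer and epithelial genes with the fall of B cell identity genes. More such cells in the lenvatinib libraries is a candidate explanation, although the sort for B cells should remove them. Of 45 list members with any read, 40 (88.9 percent) were higher in every lenvatinib library, 15 of the 18 untested members among them. Cd3g, Nkg7 and Lgals4 reached 44.5, 25.1 and 17.3. For the tested genes these counts restate the pattern, and they do not separate more such cells from a change within the sorted cells. In the DMSO libraries 12, 5 and 4 genes of these lists had a mean of at least 1, and 1 gene of the T cell list, 1 of the natural killer list and 0 of the epithelial list stand in another list. The B cell identity genes changed by unequal amounts, from −0.41 to 0.05 (Cochran's Q = 305.8, where equal changes would give about 18). This cannot decide on a lower share of B cells, since falls would also be unequal where the other cells express some of these genes. Q also rests on SEs between libraries whose spread may be technical. T cell markers rose by 0.86 more than those of macrophages and dendritic cells. The 95 percent bootstrap interval, 0.21 to 1.76, resampled genes and not libraries. Without a filter on low values these medians were 0.62 and 0.23, and with a mean filter of 5 they were 1.96 and 0.21. A lower share of B cells with the other cells in unchanged proportions would raise markers equally only where B cells do not express them. Whether they do was not tested. Apoe, Lyz2 and Cd14 of the macrophage list had DMSO means of 140, 23.6 and 11.6. The gap between the medians therefore cannot decide on this explanation. Whether the T cells are conventional ones stays open, as the ratio of the medians was 0.27, between the bounds set for either reading. A change within B cells and an effect of lenvatinib on which cells are present in the colon were not tested.

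The second pattern is the fall of interferon response genes. A lower share of B cells may add to it but, going by the list medians, does not account for its size. The median of the interferon list lay 0.53 below that of the B cell identity genes (a difference of −0.53). The 95 percent bootstrap interval, −0.94 to −0.22, resampled the genes of both lists and not the libraries, so it does not measure spread between animals. Fewer macrophages and dendritic cells are argued against by their markers as a set, as 0 of 11 tested were called lower and their median was 0.21. Single markers do not all bear this out. Cd68 and Aif1 had lower means without a call, from 7.53 ± 0.975 to 6.51 ± 1.64 and from 4.06 ± 0.669 to 3.75 ± 1.18. With an estimated correlation the rise of that list did not pass (camera adjusted p = 0.271). The scaling of the libraries is argued against as well, because under 4 other scalings the list passed and its median moved by at most 0.02. An effect of lenvatinib on interferon signalling in B cells, a different make-up of B cell subsets and a difference in handling between the groups stay open and were not tested. Gbp2 and Ifng rose while the list fell.

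The third pattern is how close the replicates of a group were. Between 2 replicates the chi-square per gene of the recovered reads was 6.74 to 9.9, where counting noise alone gives about 1, and between groups it was 29.2 to 36.76. Variation in proportion to expression, as between single animals, is argued against as what sets this spread in genes of 100 to 10000 reads: from genes of 300 to 1000 reads to genes of 3000 to 10000 reads the chi-square grew by at most 1.55 times in the 6 pairs, while it grew by 2.4 to 2.81 times in the 9 pairs between groups. Sampling of a limited number of RNA molecules, each read several times, may set the spread there, since the chi-square stayed within 1.54 times between genes of 100 to 300 reads and genes of 3000 to 10000 reads. In the 490 genes with over 10000 reads both explanations stay open. There the chi-square was 1.42 to 8.34 times that of genes of 300 to 1000 reads and 1.4 to 8.49 times that of genes of 100 to 300 reads. The highest values came from the 2 pairs with DMSO replicate 3, where 10 genes made up 60.4 and 61.5 percent of the sum, and the 4 pairs without it gave 1.4 to 3.58 times that of genes of 100 to 300 reads. If replicates were drawn from a common pool of RNA or cells per group, the adjusted p-values would not carry over to other animals, and the labels do not decide this.

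The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the only 1 of the 10 with as many calls, for genes (1854 in limma, 0 as the highest of the others, where 237 to 276 genes had an unadjusted p under 0.05) and for lists (19 in camera, 13 as the highest of the others). Every other split puts libraries of both groups on each side, so the treatment difference widens the spread within its sides. Few gene calls in those splits were therefore fixed in advance, and their list calls still hold part of that difference. They do not measure what chance gives, and no conclusion is drawn from them.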
